A study of Rattus norvegicus with 10 samples.

How the data were processed

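Total RNA of the NTS was amplified with a MessageAmp II kit and hybridised to 1-colour Affymetrix Rat 230 2.0 arrays, per the labels' protocols. The deposited table holds 1 intensity for each probe set and array on a linear scale, made with GCOS 1.2 per the submitters' processing notes. The background step, the summarisation settings and the detection calls are not given in the sources used here, so signals are not judged against background. From the values, the authors scaled each array: the mean of the intensity after trimming 2% at each end is 100 on all 10 arrays. No scanner file was used here. The table has no scan date or other batch label for the arrays.

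Samples were grouped by strain from their titles, 5 SHR and 5 WKY. The first sample of each strain has no number in its title and is called 1 here. Nothing settles whether an array holds 1 animal or a pool of 5, so the p-values measure the spread between these samples. At most 2 probe sets had identical values in any pair of arrays, so no array was a copy of another. Median SD within a strain was 0.164 log2 units in SHR and 0.136 in WKY.

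The 57 control probe sets were left out of all tests but the 3' to 5' ratios. Because the arrays were already scaled, no further normalization was applied, and log2(signal + 16) was used. Log2 differences and folds are on this scale, which understates the change of low signals, whereas the means and SDs are on the linear signal. A probe set was kept if at least 5 of the 10 arrays were at or above that array's 40th percentile, which left 18846 of 31042. Linear models with strain as the single term were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, and Benjamini-Hochberg adjusted p below 0.05 was the threshold.

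Probe sets were named from the platform's annotation, with symbols updated through Entrez identifiers to the RefSeq table of assembly GRCr8: 20826 probe sets had 1 gene symbol, 436 several and 9780 none. Of the 803 probe sets past the threshold, 230 had no symbol and 19 several, and these are not named. A gene was represented by its kept probe set of highest mean, which gave 10668 genes. Positions in the genome are not printed, since the build of the array design is not given in the sources used here. The table of GRCr8 served for names and for which genes are neighbours.

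Before the data were examined, 20 lists of pathway genes and 17 lists of markers of cell types and brain regions were fixed. Shifts of lists were tested with camera on the gene-level values with a preset inter-gene correlation of 0.01, adjusted over the 37 lists, with an estimated correlation and with fry as alternatives. The genes named were also fixed by rule: the 8 with the largest difference in each direction among those past the threshold whose SHR and WKY values did not overlap and whose higher mean reached the array median; up to 3 members of each list past the threshold, by adjusted p; 6 leukotriene genes; and 6 hypertension candidates. Further list members past the threshold (Avp, C1qb, C3, Ctss, Gstk1, Kcnd3, Kcnh3, Prlh and Txnip), and members named with values that did not pass, were named after their values were seen.

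The model was tested on simulated values of the 18846 probe sets for SHR against WKY, with means and SDs of the real arrays and 200 probe sets changed. It recovered 95.5% of those changed 2-fold, 83.6% of those changed 1.5-fold and 37.3% of those changed 1.25-fold, and 4.64% of its calls were unchanged probe sets. Noise was drawn independently for each probe set, without variation that probe sets of an array share, so these rates need not hold for the real arrays.

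Alternatives fixed beforehand were quantile normalization, a common 75th percentile, offsets of 1 and 64, no filter, a filter at the 60th percentile, eBayes without the trend or robust, array weights, the replicate number as a block, other choices of probe set for a gene, other set tests, and leaving out each array. Leaving out SHR 2 and SHR 3, the median signal of each array as a covariate, and an exact permutation test of list means were added after seeing the data.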

Results

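Gene expression was measured in the nucleus tractus solitarii (NTS), the brainstem nucleus in which baroreceptor and other visceral afferents end, of the spontaneously hypertensive rat (SHR) and the Wistar-Kyoto rat (WKY). The SHR is an inbred strain that develops high blood pressure, and the WKY is its usual normotensive control. The tissue came from male rats aged 10 to 13 weeks and was hybridised to 10 Affymetrix Rat 230 2.0 arrays, 5 for each strain. The design text calls each array an independent biological replicate, whereas the sample descriptions speak of 5 animals for a sample, so it is not clear whether an array holds 1 animal or a pool. The comparison asks which transcripts of the NTS differ between the hypertensive and the normotensive strain, and the series title points to leukotriene B4 (LTB4), a pro-inflammatory lipid mediator. The number of arrays limits the precision of each value. Arrays correlated at 0.947 to 0.988 across probe sets. SHR 1 and SHR 5 had a slightly higher mean correlation with WKY arrays (0.9749 and 0.9743) than with the other SHR arrays (0.9748 and 0.9721). The first principal component held 33.7% of the variance and ran from SHR 3 (-30.6) and SHR 2 (-21.8) to WKY 4 (20.8) and WKY 5 (23.6). SHR 5 (-0.69) lay nearest the WKY arrays. SHR 3 and SHR 2 also had the highest median signals and WKY 5 and WKY 4 the lowest, so this component does not separate strain from signal level. The median signal of an array ranged from 44.2 to 49.8 in SHR and from 39.6 to 45.7 in WKY, although every array had been scaled to the same trimmed mean.

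Of the 10668 genes tested, 437 differed between the strains, 178 of them higher and 259 lower in SHR (limma, Benjamini-Hochberg adjusted p below 0.05). Differences were mostly modest: the median absolute log2 difference of these genes was 0.42 with a median standard error of 0.088. By 2-fold or more, 13 genes were higher and 8 lower on the brightest kept probe set of each gene. A dimmer probe set could differ less or more. That of Ptprj, for example, differed by -2.08 against -0.35 on the reported one. Among the genes higher in SHR, Abhd11-as1, a non-coding transcript, had a signal of 70.0 ± 14.4 in SHR and 4.06 ± 2.71 in WKY (SD, n = 5). Ephx2, the soluble epoxide hydrolase that degrades epoxides of arachidonic acid, had 113 ± 20.1 in SHR and 23.9 ± 4.47 in WKY, a log2 difference of 1.69 ± 0.13 (SE; adjusted p = 1.48e-07). Fry, a microtubule-binding protein, had 698 ± 39.3 and 234 ± 35.01 (log2 difference 1.53 ± 0.087), although a second, dimmer probe set of this gene differed by 0.16 and did not pass the test. The class I major histocompatibility gene RT1-CE16 was 3.31-fold, the peroxisomal membrane protein gene Pxmp4 3.17-fold, the zinc finger gene Zfp597 2.76-fold, the troponin gene Tnnt1 2.53-fold and the postsynaptic scaffold gene Dlgap4 2.39-fold higher in SHR.

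Among the genes lower in SHR, Mylk, the myosin light chain kinase, had the smallest adjusted p of all genes, with a signal of 150 ± 7.57 in SHR and 570 ± 46.0 in WKY (log2 difference -1.81 ± 0.066 SE; adjusted p = 1.18e-11). Rab8b, a small GTPase of vesicle transport, had 47.7 ± 16.9 and 223 ± 16.9, a log2 difference of -1.95 ± 0.15, and a second probe set of Rab8b was lower by -1.22. Tstd1 was 2.58-fold lower in SHR, the telomere protein gene Terf2ip 2.24-fold, Vps13c 2.16-fold, the retinol saturase gene Retsat 2.04-fold, the translation initiation factor gene Eif3c 1.94-fold and the interferon-inducible gene Ifi44 1.93-fold. Where 1 strain had a very low signal the fold rests on the offset: with offsets of 64 and 1 the log2 difference ran from -0.50 to -2.01 for Vps13c, from 0.68 to 2.07 for Tnnt1, from 0.97 to 3.94 for Abhd11-as1 and from 0.51 to 1.98 for the activity gene Egr4, and all of these passed. The 5 SHR values lay entirely above or below the 5 WKY values for 615 of the tested genes, 5.76% against 0.794% by chance, and for 336 of the 437. At the level of probe sets, 803 of 18846 passed, 388 higher and 415 lower in SHR, and 52 of them differed by 2-fold or more. Leaving out SHR 2, WKY 4 or WKY 5 lowered the count of genes to 285, 256 and 245. Without both SHR 2 and SHR 3 it was 259, and with the median signal of each array as a covariate it was 104. That covariate ended the calls of 35 of the 63 named genes past the threshold, among them Pdyn, Tac1, Gucy1a1, Gucy1b1, Kcna2, Cxcl11, Ctss and C3, and not those of Ptgr1, C1r, C1s, C1qa, Lyz2, Aif1, Kcnip3 and Kcnd2. Median signal tended to be higher in SHR, so the covariate overlaps with strain and can take up part of the strain difference. Quantile normalization, which evens out the arrays without a covariate, gave 382 genes. Whether an ended call reflects signal level or this overlap was not tested.

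**Figure D1:**
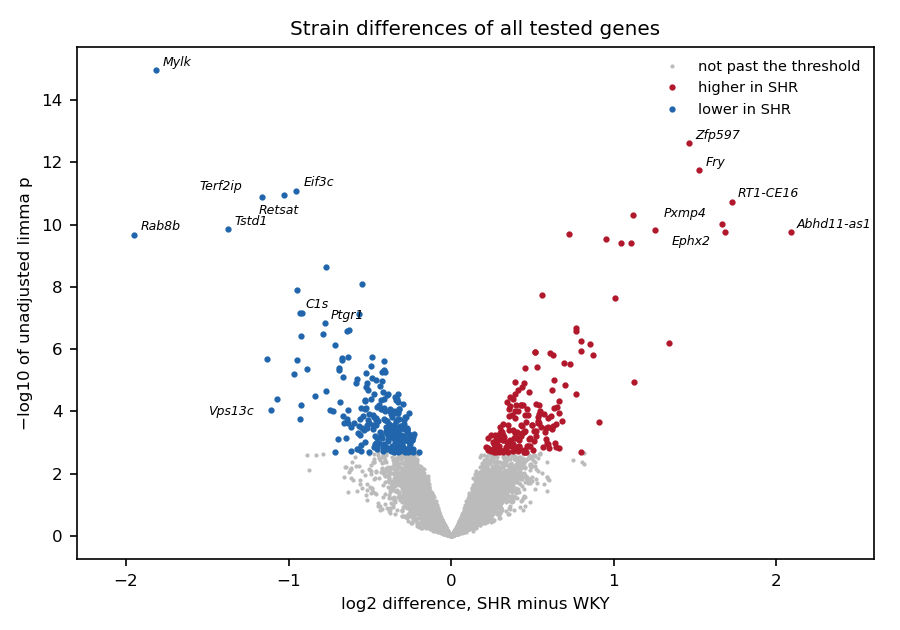
Each point is 1 of the 10668 genes tested; the horizontal axis is the log2 difference between the strains (SHR minus WKY, on log2 of signal plus 16) and the vertical axis is -log10 of the unadjusted limma p. The 178 genes higher in SHR and the 259 lower in SHR are coloured, and Mylk stands highest.

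**Figure D2:**
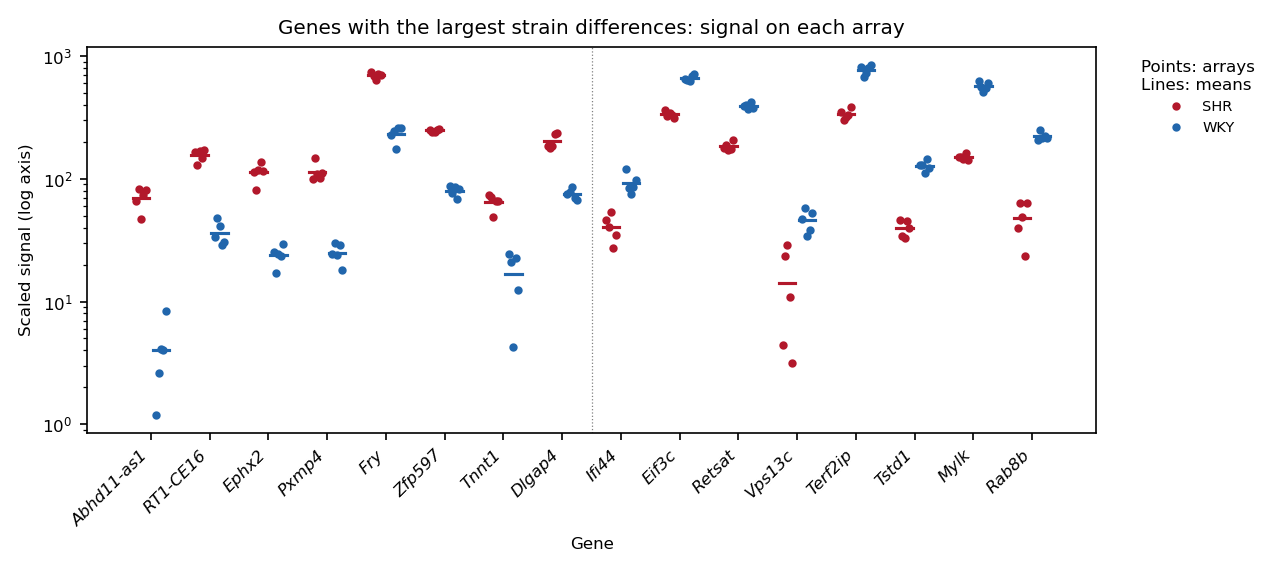
Scaled signal (log axis) of the 8 genes with the largest differences in each direction among those whose strains did not overlap and whose higher mean reached the array median, with a point for each array and a line at each strain's mean. Mylk runs from a mean of 570 in WKY to 150 in SHR.

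In the leukotriene pathway, the gene that differed was Ptgr1, which encodes the enzyme that inactivates LTB4 by oxidising it to 12-oxo-LTB4. Ptgr1 had a signal of 53.9 ± 3.91 in SHR and 104 ± 9.94 in WKY (SD, n = 5), 1.72-fold lower in SHR, with a log2 difference of -0.78 ± 0.092 (SE) and an adjusted p of 5.76e-05. All 5 SHR arrays lay below all 5 WKY arrays. No other probe set was assigned to Ptgr1 alone, so the difference could not be checked on another. Lta4h, the hydrolase that makes LTB4, had 250 ± 5.53 in SHR and 234 ± 8.56 in WKY, a log2 difference of 0.089 ± 0.058 that did not pass (adjusted p = 0.404). Alox5ap, the 5-lipoxygenase activating protein, had 31.2 ± 4.74 and 28.8 ± 5.997 (log2 difference 0.079 ± 0.14; adjusted p = 0.795), and the sign of that small difference turned with quantile normalization. The 5-lipoxygenase gene Alox5 (22.3 ± 12.5 in SHR, 15.8 ± 5.56 in WKY) and the LTB4 receptor genes Ltb4r (6.58 ± 3.32 and 9.83 ± 11.3) and Ltb4r2 (2.83 ± 0.246 and 2.29 ± 1.82) had signals too low for the filter and were not tested. Of the 16 members of this list that were tested, 1 was lower and 0 higher over all genes tested; adjusted over the list alone, 1 was lower (Ptgr1) and 1 higher, Cyp4f5 of the LTB4 omega-hydroxylase family (log2 difference 0.44 ± 0.14; adjusted p = 0.0415 over the list and 0.0812 over all genes). The list as a whole did not shift (camera, adjusted p = 0.953).

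Of 10 complement genes tested, 5 were lower in SHR and 0 higher, and 3 had differences above 0. C1s and C1r, the proteases of the first complement component, had signals of 82.3 ± 11.6 and 72.5 ± 11.8 in SHR against 172 ± 24.7 and 124 ± 8.79 in WKY, log2 differences of -0.93 ± 0.10 and -0.67 ± 0.097 (adjusted p = 2.91e-05 and 0.000499). C1qa, C1qb and the central component C3 were lower by -0.42, -0.46 and -0.33, while C1qc and the C1 inhibitor gene Serping1 differed by -0.15 and -0.22 and did not pass. Adjusted over the list alone 6 were lower. The list's median log2 difference was -0.28 (camera adjusted p = 0.000133; adjusted p = 0.240 with an estimated correlation). Without the filter on dim probe sets the median was -0.0069 and the call ended (adjusted p = 0.0523).

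Of the markers of microglia and macrophages, 5 of 14 were lower in SHR; C1qa, C1qb and C1qc also stand in the complement list. Lyz2, the macrophage lysozyme, had 201 ± 11.2 in SHR and 272 ± 10.9 in WKY (log2 difference -0.40 ± 0.063; adjusted p = 0.00095), and Ctss, a lysosomal cathepsin, had 1008 ± 64.4 and 1222 ± 55.2 (-0.28 ± 0.057; adjusted p = 0.0103). Aif1 was lower by -0.52 ± 0.089, but its second, dimmer probe set differed by 0.51 ± 0.18 in the opposite direction and did not pass (adjusted p = 0.124). None of the 14 was higher over all genes, 6 were lower over the list alone, and 13 of the 14 differences were below 0, the exception being Cx3cr1 (0.19 ± 0.15). The median log2 difference of the list was -0.16 (camera adjusted p = 4.65e-06; adjusted p = 0.0241 with an estimated correlation). In an exact permutation test over the arrays of each list's mean, chosen after the data were seen, the microglia and complement lists both reached the smallest p that 252 assignments allow, 0.00794, with an adjusted p of 0.0979 over the 37 lists. The 3 markers of blood leukocytes reached the same p with a higher mean in SHR.

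**Figure D3:**
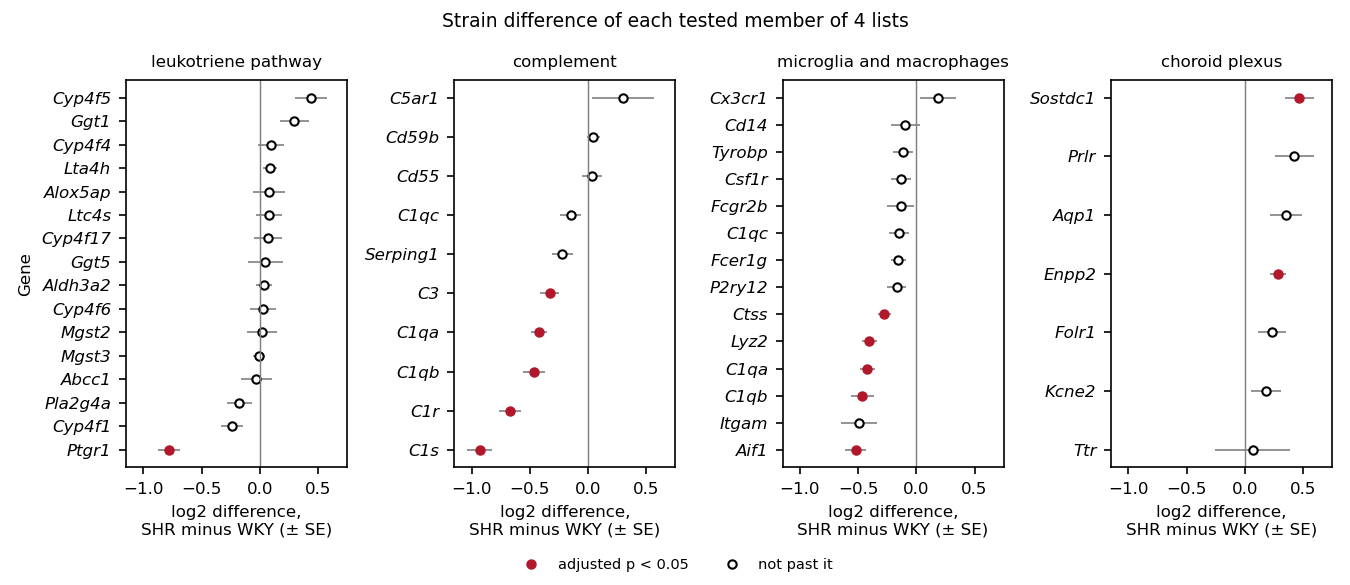
The log2 difference between the strains (SHR minus WKY, with its standard error) of each tested member of 4 lists; filled points passed the threshold over all genes tested. Ptgr1 stands alone at -0.78 in the leukotriene list, whereas 5 of 10 complement genes and 5 of 14 microglia markers were lower in SHR.

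Markers of the choroid plexus and genes of ribosomal proteins were higher in SHR as lists by camera with its preset correlation, a call that an estimated correlation ended for both. Of the 7 choroid plexus markers tested, Enpp2 (748 ± 50.6 in SHR, 612 ± 62.3 in WKY; log2 difference 0.28 ± 0.070) and Sostdc1 (46.1 ± 7.33 and 28.7 ± 2.62; 0.47 ± 0.12) were higher and 0 lower, with 4 higher over the list alone, and the list's median was 0.28 (camera adjusted p = 0.00484; adjusted p = 0.281 with an estimated correlation). Ttr, the leading transcript of that tissue, had a mean of 58.1 in SHR and 67.0 in WKY, or 38.2 without WKY 1, which stood at 182. Its log2 difference was 0.068 ± 0.32, and 0.45 ± 0.21 without WKY 1 (adjusted p = 0.252). Of 43 ribosomal protein genes 1 was higher, Rps29 (log2 difference 0.29 ± 0.070), and 3 over the list alone. The median of this list was 0.071 (camera adjusted p = 0.00108; adjusted p = 0.780 with an estimated correlation). In the exact permutation test of list means their adjusted p was 0.235 and 0.323, quantile normalization ended the ribosomal call, and the median-signal covariate and the lack of a filter (adjusted p = 0.373) ended the choroid plexus call.

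Voltage-gated potassium channel genes held 4 members lower and 1 higher in SHR among 24 tested, without a shift of the whole list (camera adjusted p = 0.462); over the list alone 5 were lower and 3 higher. Kcnip3, an auxiliary subunit of A-type channels, had a signal of 88.4 ± 14.5 in SHR and 180 ± 21.5 in WKY (log2 difference -0.91 ± 0.10; adjusted p = 2.91e-05), and Kcnd2, an A-type pore subunit, had 293 ± 11.6 and 395 ± 24.3 (-0.41 ± 0.060; adjusted p = 0.000506; -0.35 on a second probe set, which did not pass). Kcna2 was lower by -0.34 ± 0.063 on 1 probe set and differed by 0.098 on another. For Kcnd3 the probe sets disagreed, with -0.46 ± 0.12 on the brighter and 0.86 on the dimmer, and both passed the test. Kcnh3 was higher (0.45 ± 0.12; adjusted p = 0.0494). This call ended in 8 of 10 fits with 1 array left out. Of 20 sodium and calcium channel genes 1 was lower, Scn2b (-0.26 ± 0.064; list adjusted p = 0.953), also over the list alone.

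Among 35 neuropeptide and receptor genes tested, 4 were lower and 1 higher in SHR, with the same counts over the list alone and no shift of the list (camera adjusted p = 0.744). Pdyn, the prodynorphin gene, had 343 ± 46.4 in SHR and 496 ± 31.8 in WKY (log2 difference -0.52 ± 0.081; adjusted p = 0.00103), although a dimmer probe set differed by -0.0023. Tac1, the precursor of substance P, was lower by -0.33 ± 0.069, the neurokinin B receptor gene Tacr3 by -0.56 ± 0.13, and Prlh, the prolactin-releasing hormone gene, by -0.42 ± 0.11. Avp, the vasopressin gene, was higher (53.0 ± 15.1 in SHR, 27.9 ± 7.16 in WKY; log2 difference 0.64 ± 0.16; adjusted p = 0.0336). The calls of Avp and Prlh ended with quantile normalization.

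Genes of nitric oxide signalling included subunits of soluble guanylate cyclase, the nitric oxide receptor. Gucy1a1 had a signal of 206 ± 18.5 in SHR and 152 ± 11.8 in WKY (log2 difference 0.40 ± 0.076; adjusted p = 0.00604), whereas its dimmer probe set differed by 0.18 and did not pass (adjusted p = 0.530). The mean of both did not pass either (adjusted p = 0.107). Gucy1b1 had 419 ± 49.6 and 551 ± 65.8 (-0.38 ± 0.086; adjusted p = 0.0170), and its second probe set was lower by -0.44. These were the 2 members that passed among 16 tested, also over the list alone (camera adjusted p = 0.474). Of 40 glutathione and antioxidant genes 4 were lower and 1, Ephx2, higher, with 6 lower and 2 higher over the list alone (camera adjusted p = 0.474). The lower members were Gsta1 (-0.32 ± 0.063), Gstm7 (-0.35 ± 0.081) and Gstk1 (-0.28 ± 0.069), all glutathione transferases, and the thioredoxin inhibitor Txnip (-0.29 ± 0.077). The calls of these lower members all ended with the median-signal covariate and without both SHR 2 and SHR 3.

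In the list of cytokines, chemokines and their receptors 2 of 21 tested members were lower and 1 was higher (3 and 2 over the list alone; camera adjusted p = 0.953). Cxcl11, an interferon-inducible chemokine, had 41.4 ± 7.67 in SHR and 19.9 ± 5.19 in WKY (log2 difference 0.68 ± 0.15; adjusted p = 0.0121), and the receptor gene Tnfrsf1a was lower by -0.42 ± 0.11. That call ended in 8 of 10 fits with 1 array left out. Cxcl14 was lower by -0.41 ± 0.076 on its brighter probe set, while its dimmer probe set differed by 0.42 and did not pass. Of 17 antigen presentation genes RT1-CE16 was higher and RT1-DMa, of the class II pathway, lower (-0.40 ± 0.093; list adjusted p = 0.462), with 2 higher and 1 lower over the list alone. Among 19 genes of leukocyte adhesion and endothelial junctions, Vcam1 was lower (-0.27 ± 0.066; list adjusted p = 0.977), with 2 lower and 1 higher over the list alone. F11r, the junctional adhesion molecule that was fixed as a hypertension candidate, had 89.2 ± 21.3 in SHR and 73.7 ± 13.7 in WKY, a log2 difference of 0.22 ± 0.13 (adjusted p = 0.375).

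The other hypertension candidates did not pass in the main fit. Agt, the angiotensinogen gene, had 2378 ± 147 in SHR and 2217 ± 116 in WKY (log2 difference 0.10 ± 0.058; adjusted p = 0.348), a small difference whose sign turned with quantile normalization. The angiotensin receptor gene Agtr1a differed by -0.055 ± 0.092 (adjusted p = 0.784). The tyrosine hydroxylase gene Th had 416 ± 19.1 and 477 ± 67.8 (-0.18 ± 0.079; adjusted p = 0.201), and the dopamine beta-hydroxylase gene Dbh had 272 ± 28.7 and 334 ± 51.1 (-0.27 ± 0.094; adjusted p = 0.110). Without WKY 3 the difference of Dbh passed (adjusted p = 0.0406). The neuronal nitric oxide synthase gene Nos1, at 32.6 ± 5.62 and 25.6 ± 7.96, was too low for the filter. Of 9 genes of the renin-angiotensin system and 17 of catecholamine synthesis, transport and receptors, 0 passed in limma, also over each list alone, and 1 and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.387 and 0.953). An unadjusted p that low was common over all genes: the limma p of Th, 0.0347, had an adjusted p of 0.201.

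Several lists held 1 or 2 differing members and no shift. Over all genes tested 4.10% passed, so lists of this size can hold such a member by chance. These members are not read as a change of their pathway. Lower in SHR were Abat (-0.43 ± 0.10) among 15 GABA genes, Glul (-0.35 ± 0.069) among 22 glutamate genes, Ptgds (-0.30 ± 0.073) among 11 prostanoid genes and 15 meningeal markers, Epas1 (-0.24 ± 0.059) among 16 genes of angiogenesis and hypoxia, Hspb8 (-0.38 ± 0.088) among 24 heat shock and unfolded protein genes, and Ndufv3 (-0.29 ± 0.061) among 81 genes of oxidative phosphorylation. Other kept probe sets of Glul differed by 0.12 and 0.01, that of Ndufv3 by 0.31 and that of Hspb8 by -0.19, none of which passed. Probe sets too dim for the filter differed by 0.21 and 0.45 for Abat and by 0.25 for Epas1, opposite to the reported ones. With 1 array left out the calls of Ptgds and Epas1 ended in 7 of 10 fits, and both also ended with the covariate and without the trend. With the mean of a gene's kept probe sets the calls of Glul, Ndufv3 and Hspb8 ended. The activity gene Egr4 was higher (43.7 ± 9.55 in SHR, 11.8 ± 7.54 in WKY; log2 difference 1.13 ± 0.19), the 1 of 20 immediate early genes to pass. The median-signal covariate ended that call (adjusted p = 0.0892). Adjusted over the list alone, 3 GABA genes were lower and 1 higher and 1 glutamate gene was lower and 1 higher, and the other lists kept their counts. The camera adjusted p of these lists lay between 0.744 and 0.974. For the GABA and prostanoid lists the median and mean were above 0 while the test pointed lower, and for the angiogenesis list, as for leukocyte adhesion, the median was below 0 while the mean was above 0 and the test pointed higher.

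Markers of other cell types and of neighbouring tissue were tested for the make-up of the samples. Neuronal markers held 1 higher member of 17, Snap25 (0.33 ± 0.090; list adjusted p = 0.184), and astrocyte markers held Aldoc higher (0.28 ± 0.076) and Glul lower among 14 (list adjusted p = 0.398). Mobp (-0.34 ± 0.072) was lower among 13 oligodendrocyte markers (list adjusted p = 0.387). Its other probe sets differed by -1.41, which passed in limma (adjusted p = 9.68e-09), and by -0.022, which did not. Vwf was lower (-0.52 ± 0.11) among 15 endothelial markers, Mylk among 8 markers of pericytes and vascular smooth muscle, and Hoxb3 (-0.35 ± 0.079) among 11 Hox genes, while Cd4 (0.52 ± 0.12) was higher among 3 markers of blood leukocytes. By camera none of these 4 lists shifted, with adjusted p of 0.462, 0.953, 0.337 and 0.337, and the pericyte list had a median above 0 but a mean below 0 and a test pointing lower. With fry, which does not set a list against other genes, the pericyte list passed (adjusted p = 0.0235, lower). However, 6 of its 8 members had differences above 0, and Mylk alone was the member that passed, at -1.81. In the exact permutation test of list means the pericyte list had an adjusted p of 0.415. Adjusted over the list alone, 3 astrocyte, 2 endothelial and 1 oligodendrocyte markers were higher and 1 of each was lower, and the counts of the neuronal, pericyte, Hox and leukocyte lists were as over all genes. Markers of oligodendrocyte precursors, ependyma, cholinergic and serotonergic neurons, cerebellum, forebrain and red blood cells held 0 differing members over all genes, with list adjusted p from 0.337 to 0.977. Of their 38 members 8 had an unadjusted p under 0.05 in limma. Values this low were common over all probe sets, where a limma p of 0.0498 had an adjusted p of 0.237. The 8 are therefore not read as a difference of these markers. Over the list alone 1 precursor marker was lower, and 1 forebrain marker was lower and 1 higher; the ependymal median was above 0 and its mean below 0. With quantile normalization the calls of Aldoc, Snap25, Cd4, Sostdc1, Rps29, Vcam1, Ndufv3, C3, Gstk1, Txnip, Kcnd3 and Kcnh3 ended. With 1 array left out the calls of Aldoc and Sostdc1 ended in 8 of 10 fits, those of C3, Snap25 and Txnip in 7, and those of Gstk1, Kcnd3 and Prlh in 6.

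RNA integrity was read from the control probe sets at both ends of 2 transcripts. The log2 ratio of 3' to 5' signal of beta-actin was 1.60 ± 0.285 in SHR and 1.59 ± 0.147 in WKY (SD, n = 5), a difference of 0.013 (exact permutation test, two-sided, p = 0.937). That of GAPDH was 0.253 ± 0.102 and 0.156 ± 0.0625, a difference of 0.097 (exact permutation p = 0.0794; adjusted over both transcripts 0.159).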

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

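The tests of the explanations for the microglia and choroid plexus patterns were chosen only after the results were seen. An array was singled out where its gap to the nearest other array of its strain exceeded 0.71 of that strain's range, which chance gives in about 1 in 20 groups. Of 152 groups of 5 values 6 did so. C1qa was lowest on WKY 2 (0.793 of the range; 9.01 against a mean of 9.28 on the other WKY arrays, log2), Ptgr1 was highest on SHR 1 (0.729; 6.26 against 6.09), and Gucy1a1 was highest on SHR 3 (0.744; 7.99 against 7.74). Pxmp4 was highest on SHR 2 (0.712; 7.36 against 6.93), Ndufv3 was lowest on WKY 5 (0.753; 8.83 against 9.04) and Sostdc1 was highest on WKY 5 (0.836; 5.62 against 5.44). The outlying arrays of C1qa, Ptgr1, Ndufv3 and Sostdc1 lie toward the other strain.

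The lower microglia and macrophage markers may come from a lower share of these cells, from a few regulated members, or from the arrays that stand apart. A lower share acting alike on every marker would give equal falls. The 9 markers with a mean signal of at least 100 fell unequally, from -0.52 for Aif1 to -0.13 for Csf1r. Their heterogeneity was 3.76 against a 95th percentile of 2.20 under a common shift. These values argue against equal falls on these probe sets. Transcripts that other cells also hold, or unlike background of the probe sets, could still make the falls unequal. The second probe set of Aif1 differed by 0.51 in the opposite direction. A lower share is therefore not excluded. SHR 2 and SHR 3 are argued against, since without them the list's median was -0.22 and its camera adjusted p 1.84e-06. A few members alone stay open: when the 9 markers that did not pass were replaced by random genes of like signal, 23.5% of 10000 draws gave a median as low. Every draw kept the 5 members that passed, which holds its median down (-0.10 at the median of the draws). The test could therefore hardly exclude this explanation. It also does not weigh that 13 of the 14 differences were below 0. The biological difference between the strains in these cells was not tested apart from these values.

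The higher choroid plexus markers could come from choroid plexus carried along in dissection, which would bring Ttr, its most abundant transcript. Ttr had a log2 difference of 0.068 ± 0.32 (SE), below that of Enpp2 by 0.662 and below that of Sostdc1, the largest among the other markers, by 1.172 standard errors of the difference. This test replaced an earlier one that set signals of different probe sets against each other, which are not on a common scale. Tissue carried along therefore cannot be told apart from expression for Enpp2 or for the other markers. WKY 1 had a Ttr signal of 182 against 26.9 to 62.2 on the other WKY arrays; without it Ttr had a log2 difference of 0.45 ± 0.21 and did not pass (adjusted p = 0.252).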

How the results depend on the processing

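The fits without SHR 2 and SHR 3, with the median signal as a covariate and the exact permutation of list means were chosen after the data were seen. Where a value moved the cause was not tested, except that leaving out arrays also lowers power. The covariate overlaps with strain, which lowers power too. Of the 63 named genes past the threshold, 54 were tested under all alternatives; 50 of these had the same direction and 21 passed under all. The other 9 were too dim for the filter at the 60th percentile; under the remaining alternatives all 9 kept their direction and 3 passed. With any 1 array left out 38 of the 63 passed. The other 25 lost their call in at least 1 such fit: Aldoc, Kcnh3, Sostdc1 and Tnfrsf1a in 8 of 10; C3, Epas1, Ptgds, Snap25 and Txnip in 7; Gstk1, Kcnd3 and Prlh in 6; Avp, Enpp2, Rps29 and Vcam1 in 5; and Abat, Scn2b, Tacr3, Gstm7, Gucy1b1, Cd4, Hspb8, RT1-DMa and Vwf in 4 or fewer. Dbh alone gained a call, without WKY 3 (-0.34; adjusted p = 0.0406). Leaving out 1 array gave 480 to 976 probe sets, 245 to 530 genes (245 without WKY 5, 256 without WKY 4, 285 without SHR 2; 480 probe sets without WKY 4, 481 without WKY 5) and 2 to 4 marker lists (4 without WKY 4). The 3' to 5' difference of beta-actin then ran from -0.0727 to 0.123, and that of GAPDH from 0.0548 to 0.124, with an exact permutation p of 0.0476 without SHR 1 and 0.0238 without WKY 3. Without both SHR 2 and SHR 3 there were 512 probe sets and 259 genes, and beta-actin differed by -0.0838. With the median-signal covariate 206 probe sets, 104 genes and 2 leukotriene genes passed, and the choroid plexus median was 0.062 (adjusted p = 0.428). Quantile normalization left 1 gene list, with a ribosomal median of 0.016 (adjusted p = 0.978), and put 40.1% of called probe sets higher in SHR against 48.3%. Probe sets of 2-fold or more numbered 113 with an offset of 1, 14 with an offset of 64 and 32 with the filter at the 60th percentile. With no filter 1 gene list and 1 marker list passed; complement had a median of -0.0069 (adjusted p = 0.0523) and choroid plexus 0.21 (adjusted p = 0.373). Without the trend 2 leukotriene genes passed. Leaving out the trend also ended 17 calls: Abat, Aldoc, C3, Enpp2, Epas1, Gstk1, Gstm7, Gucy1b1, Kcnd3, Kcnh3, Prlh, Ptgds, Rps29, Scn2b, Snap25, Txnip and Vcam1. With an estimated correlation 0 gene lists and 1 marker list passed (1 and 2 at an unadjusted p under 0.05), the medians of complement (-0.28), ribosomal proteins (0.071) and choroid plexus (0.28) missing the threshold at adjusted p = 0.240, 0.780 and 0.281. With fry 1 gene list and 3 marker lists passed, the ribosomal median of 0.071 having an adjusted p of 0.224. In the exact permutation of list means 0 gene lists and 0 marker lists passed, 7 having an unadjusted p under 0.05; complement (-0.28) and microglia (-0.16) had an adjusted p of 0.0979, choroid plexus (0.28) 0.235 and ribosomal proteins (0.071) 0.323. Over all alternatives the adjusted p ran from 9.3e-07 to 0.0979 for microglia, 1.67e-05 to 0.240 for complement, 0.000936 to 0.428 for choroid plexus and 2.17e-06 to 0.978 for ribosomal proteins.

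Signs turned for Agt (-0.016) and Alox5ap (-0.054) with quantile normalization. That of Alox5ap was -0.041 with the covariate and ran from -0.0053 (without WKY 5) to 0.14 with 1 array left out. With the probe set of largest variance Aif1 was at 0.51, Cxcl14 at 0.42, Ndufv3 at 0.31 and Kcnd3 at 0.86, and with the mean of a gene's probe sets Cxcl14 was at 0.0042, Ndufv3 at 0.012 and Kcnd3 at 0.20. The largest-variance choice also ended the calls of Gucy1a1, Hspb8 (adjusted p = 0.490), Kcnd2, Aldoc and Kcnh3, and the mean those of Aif1, Glul, Gucy1a1, Hspb8 (adjusted p = 0.122), Kcna2, Aldoc and Snap25. With the replicate number as a block 1214 probe sets and 661 genes passed; the numbers were not taken to pair the samples, because the deviations of same-numbered arrays correlated at 0.038 to 0.28 and not above 0.1 for every number. That 6 of 10 arrays, those numbered 2, 3 and 5, correlated best with their own number is a hint from the data, and pairing stays open. Detection calls were not used here, so how far dim signals stand above background is unknown.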

Other observations

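The tests of other probe sets, of neighbouring genes and of other splits of the arrays were fixed before their results were seen, whereas the genes named in the next sentences were picked after their values were seen. Some differing genes were neighbours among the tested genes in the gene order of GRCr8, where genes that were not tested can lie between them. C1r and C1s lie side by side in this order and were both lower in SHR, as were Hacd2 (-0.40) and Mylk, and Lrif1 (-0.50), Cd53 (-0.39) and Kcna2. Tapt1 (1.01) and Prom1 (0.52) were neighbours that were both higher. A run of 4 adjacent tested genes had alternating directions, with Ltbr (0.54) and Cd9 (0.52) higher and Tnfrsf1a (-0.42) and Vwf (-0.52) lower. Gucy1a1 and Gucy1b1, the guanylate cyclase subunits with opposite differences, are neighbours too.

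A hypothesis is that part of the differing genes lie in blocks of chromosome that differ between the strains. Among 10662 tested genes in chromosome order, 435 of them differing, 27 adjacent pairs both differed against 17.7 expected (10000 random placements, one-sided permutation p = 0.0206), which is consistent with such blocks. Of the 27 pairs 12 had the same direction and 15 opposite ones. Neighbours that are regulated together could give such pairs without any difference in sequence, and this was not tested.

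Strain variants under the probes are a candidate explanation for differences seen on a single probe set. Ptgr1, C1r, C1s, Ephx2 and Zfp597 have no other probe set, so the comparison below does not cover them. For genes differing by 1.5-fold or more, other kept probe sets existed for 17 of 95, and the median ratio of their log2 difference to the reported one was 0.241 (95% bootstrap interval 0.106 to 0.628), with the same sign in 14 of the 17; another probe set passed in the same direction for 5 of these genes and in the opposite direction for 1. For smaller differences the ratio was 0.191 (0.0086 to 0.337) over 103 of 342 genes, with the same sign in 63 of the 103. In that part another probe set passed in the same direction for 10 genes and in the opposite direction for 6. Both intervals lie below full agreement, but the other probe sets are dimmer by construction and the offset shrinks their differences, so variants under the probes cannot be told apart from expression in either part.

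Among 100 splits of the 10 arrays into 5 and 5, the strains gave 803 probe sets, 52 of 2-fold or more and 437 genes. The other splits gave at most 2 for each count. Of the 100, 1 split, the real one, reached each, so a grouping by chance is unlikely for these counts. The other splits mix the strains, so strain differences widen their spread and hold their counts down. Their counts do not estimate false calls. Nor can the splits tell strain from any processing that ran with strain. Chance cannot be excluded for the number of shifted lists: 25 of the 100 splits gave at least the 4 lists seen, with up to 8 in another split.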
